A study of Mus musculus with 6 samples.

How the data were processed

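DNA recovered with even or odd biotinylated probes against Tug1 RNA was analysed from 4 pulldown libraries of mouse podocytes, 2 per probe set. Per the labels' protocols, the podocytes carry a temperature-sensitive SV40 T antigen, grew at 33 degrees and differentiated at 37 degrees for 10 days, at passages 10 to 12; nuclei crosslinked with glutaraldehyde were sonicated, 1% of the chromatin was kept as input, and DNA of 200 to 400 bp was sequenced on an Illumina instrument. The values of 2 input libraries were not analysed here. A pulldown with probes against an unrelated RNA was not analysed here either.

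Reads were aligned with Bowtie2 2.1.0 to mm10, per the submitters' processing notes. The deposited files are 1 peak list per pulldown, and per the file names each was called against 1 input library, inputs 1 and 2 for pulldowns numbered 1 and 2, without pooling of replicates. Peak names in the files start with MACS, and the version, threshold and handling of duplicate reads are not given in the sources used here. The deposited score of each peak comes from the authors' peak caller; its scale is not stated in the files, many peaks share a value of 3100 (31995 of even replicate 1 and 28026 of odd replicate 1) and few exceed it (788, 2, 0 and 4 in even replicates 1 and 2 and odd replicates 1 and 2), and it was used within each list, to compare medians and to give percentiles, which were combined over the lists only to order regions for naming. A series-wide deposited list of 130269 peaks was identical to the 4 lists joined and added nothing. Peak lists carry no read counts, so depth is unknown and no counting interval was formed; a deeper library can yield more peaks, which limits every comparison of peak numbers.

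Positions are given 1-based on mm10. Genes came from a RefSeq gene table of the same build (49943 genes) with start, end and kind of gene but neither strand, exons nor transcription start sites. For this reason the planned classes of promoter, exon and intron were replaced by the kind of gene holding the centre of a region and by distance to either gene end, the planned window upstream of Ppargc1a by 500 kb to each side, and the planned exclusion of assembly gaps by placement between the first and last peak of each chromosome.

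Peaks overlapping by at least 1 bp were merged across libraries into regions. Chance was taken from 1000 random placements that kept the width and chromosome of every peak, with one-sided empirical p-values for overlap and two-sided ones for gene classes (smallest possible 0.001 and 0.002). Fixed gene lists were set against 10000 random lists of protein-coding genes, each member drawn among the 200 nearest in gene length. Median scores of shared and unshared peaks were compared by a permutation test with 100000 resamples. Adjustment was by Benjamini-Hochberg over the 6 pairs, 6 gene classes, 11 lists or 4 libraries, with a threshold of 0.05. Tests of small RNA genes, added after seeing the data, were adjusted over 12 combinations of gene kind and library, and those of shared regions by kind of gene over 8 kinds. Mean enrichment within and between probe sets was compared by an exact test over the 3 pairings of 4 libraries. Genes, regions and peaks are not independent replicates, and placement and permutation p-values describe these 4 lists.

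The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Tug1 and Ppargc1a, the 20 regions in all 4 libraries with the best rank in their lowest-ranked library (ties, which decided the choice, were broken by mean percentile and then position), and up to 4 genes per list with a region in all 4 libraries. Genes named for regions of at least 1 even and 1 odd library, and genes holding several regions, were picked after their values were seen. Alternatives were a reciprocal overlap of 50%, peaks at or above the median score, shifts of 10 to 100 kb in place of random placement, autosomes alone, same-number pairs alone, other gene windows, and each library left out in turn. Exclusion of chromosomes 8, 15 and 19, and of 8 repeated stretches with chromosomes Y and M or with both sex chromosomes and M, was added after seeing the data.

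The procedure was tested on simulated data. A pair of unrelated lists, placed at random in the way used for chance, gave a 1.00-fold overlap. This checks the calculation, not whether random placement describes real peaks. In simulated lists, 500 of 500 planted shared regions were found and 0 without planting. Random lists of 40 genes reached p at or below 0.05 in a share of 0.01. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.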

Results

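Chromatin recovered with probes against the long noncoding RNA Tug1 was mapped in cultured mouse podocytes, the glomerular epithelial cells whose foot processes form the kidney's filtration barrier, by chromatin isolation by RNA purification and sequencing (ChIRP-seq). In this assay, biotinylated oligonucleotides complementary to an RNA are used to pull that RNA and its crosslinked chromatin out of a nuclear extract, and the recovered DNA is sequenced. The 48 probes along Tug1 were divided into an even and an odd set, which share the target RNA but no probe, and each set was used in 2 pulldowns. The 4 pulldown libraries came with 2 libraries of input DNA, which entered only through the authors' peak calling, the replicate 1 pulldowns against input 1 and the replicate 2 pulldowns against input 2. The even lists held 40725 and 26529 peaks (mean 33627 ± 10038, SD, n = 2), and the odd lists held 28047 and 34968 (mean 31508 ± 4894, SD, n = 2), so the probe sets differed by less than their replicates did. Peaks covered 16 and 11 Mb in even replicates 1 and 2 and 7.76 and 14.7 Mb in odd replicates 1 and 2, with median widths of 399, 404, 247 and 407 bp. The read depth of the libraries is unknown from peak lists. Nothing in the labels says whether replicates were separate cultures, so the spread between them may be technical.

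The first question was whether the probes recovered the Tug1 locus itself, the usual positive control of the assay. Probes complementary to Tug1 RNA can also bind the DNA of the gene directly. Peaks there, in either probe set, therefore do not by themselves show recovery through the RNA. Tug1 (gene ID 544752) is a 9030 bp lncRNA gene at chromosome 11, positions 3639785 to 3648814 of mm10. All 4 pulldowns had peaks inside it, 3 in each even library, 5 in odd replicate 1 and 3 in odd replicate 2, and these covered 59.9% and 53.1% of the gene in the even and 38.0% and 53.4% in the odd libraries. They merged into 3 regions present in all 4 libraries, at 3639932 to 3643278, 3644508 to 3645706 and 3646355 to 3647222. The first, 3347 bp wide, had a score of 3100 in every library, the value at which scores pile up. At the other two regions the score was 1725 and 1199 in even replicate 2 and 1394 and 1085 in odd replicate 2, each above the 99.1 percentile of its own list. Only even replicate 1 had further peaks within 50 kb of the gene, 3 of them, from 3675652 to 3698196. The exon structure of Tug1 was not used here, so the regions are placed in the gene but not in exons or introns.

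**Figure D1:**
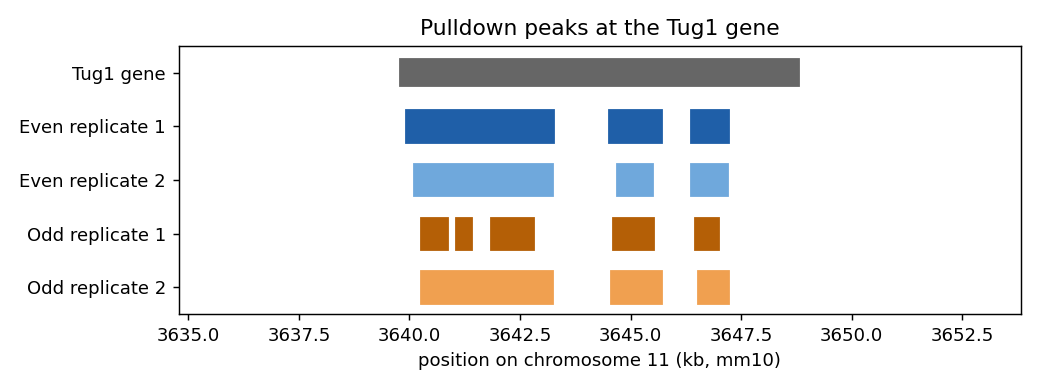
Peaks of the 4 pulldown libraries (coloured bars, 1 line per library) and the Tug1 gene (grey bar) along chromosome 11 in kb of mm10. The peaks of all 4 libraries fall in the same 3 parts of the gene, and odd replicate 1 splits the widest part into 3 peaks.

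The next question was how far the pulldowns recovered the same places genome-wide, within a probe set and between the sets. Between the even lists, 5288 peaks (13.0%) of replicate 1 and 5307 of the 26529 peaks of replicate 2 overlapped a peak of the other by at least 1 bp. Averaged over both directions, 16.5% of peaks overlapped between the even lists and 11.5% between the odd lists, against 1.09% and 0.869% after random placement, which is 15.1-fold and 13.2-fold. The 4 even-odd pairs overlapped at 12.7% (both replicates 1), 12.6% (even 1 with odd 2), 6.50% (even 2 with odd 1) and 6.68% (both replicates 2), or 13.9-fold, 10.2-fold, 8.68-fold and 6.36-fold over chance. For each of the 6 pairs the one-sided permutation p was 0.001, also after Benjamini-Hochberg adjustment, the smallest that 1000 placements can give. Mean enrichment was 14.2-fold within probe sets (SD 1.33, 2 pairs) and 9.77-fold between them (SD 3.15, 4 pairs), a difference that 4 libraries cannot test, since the exact p over the 3 ways of pairing them is 0.333 at its smallest.

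**Figure D2:**
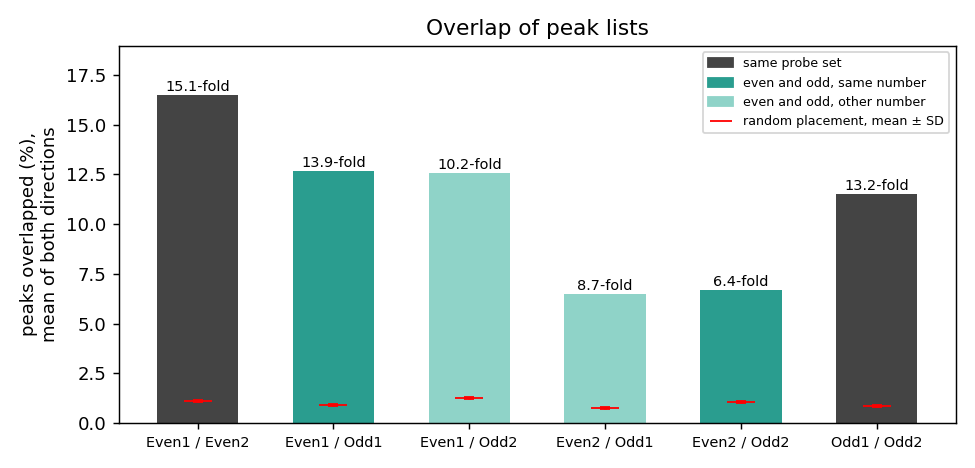
Percent of peaks that overlapped a peak of the other list by at least 1 bp, averaged over both directions, for the 6 pairs of libraries (bars, with the fold over chance above each). Red marks give the mean ± SD of 1000 random placements, and every bar lies far above its mark, from 6.36-fold to 15.1-fold.

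Regions recovered by both probe sets in both replicates numbered 748. They included Tug1 with 3 regions, Ulk4, which codes for a pseudokinase, also with 3, and 9 other genes with 2 each. These were the Ras exchange factor gene Sos2, the chloride channel gene Ano2, Phactr2, Limch1, Csgalnact1, Cfap20dc, Eppk1, Gm21119 and 4930467E23Rik. Longer genes hold more regions by chance, and gene length was not allowed for in these counts. In total 342 of the regions overlapped a protein-coding or lncRNA gene, 329 different genes. By kind, 269 overlapped a protein-coding gene against 290 by random placement, and 86 a lncRNA gene against 64.0, where a region could count in both. Random placement of the 4 lists gave 0.172 ± 0.411 (SD) regions in all 4 and at most 2, a 4349-fold difference (one-sided permutation p = 0.001, the smallest possible). The fold depended on how chance was drawn: it was 65.7 when peaks were shifted by 10 to 100 kb, and 88.0 when the 5259 regions of both even and the 3536 of both odd lists were placed as wholes. It also depended on what was counted. It was 13730 for peaks at or above the median score (508 regions) and 27034.5 for stretches covered by all 4 lists (784 stretches). These 748 made up 0.661% of the 113114 merged regions, of which 88.6% came from 1 library, 8.72% from 2 and 2.06% from 3. Leaving out a library left 887 regions common to the others without even replicate 1, 1903 without even replicate 2, 1246 without odd replicate 1 and 1305 without odd replicate 2.

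Ranked by their lowest percentile over the 4 lists, 506 of the 748 regions tied at the top, at the percentile of a score of 3100 in odd replicate 1. The first 20 were therefore set by the tie-break, the mean percentile and then position, and 12 of them lay inside genes and 8 outside. Protein-coding hosts were Faxc (chromosome 4, 21947977 to 21948771), Ano2 (chromosome 6, 125876656 to 125877527), Gm40862, Rasgrf2, an exchange factor for Ras (chromosome 13, 92043813 to 92044273), Dpp9, a cytosolic dipeptidyl peptidase (chromosome 17, 56199533 to 56200529), and Qpct, glutaminyl cyclase (chromosome 17, 79087189 to 79088928). Host lncRNA genes were Tug1, D130079A08Rik, Gm34259, Gm31706, Gm33838 and Gm36903. Of the regions outside genes, 2 lay nearest to Gm33780 in a repeated stretch of chromosome 2, and the others nearest to Asmt, which codes for the last enzyme of melatonin synthesis (80010 bp away), the beta-defensin gene Defb41 (129611 bp), Gm8882, Gm39613, Gm34609 and Rab10os. Defb41 came first through a score of 3233.1 in even replicate 1, with 484 and 361 in even and odd replicate 2. A score of at least 3100 in all 4 libraries was found at 14 of the 20 regions and at no other shared region. In the replicate 1 lists, 80.5% of even and 99.9% of odd peaks were at or above that value, against 0.0716% and 0.112% in the replicate 2 lists.

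Peaks shared by all 4 libraries scored higher than peaks found in 1 library where the score had room to vary. In even replicate 2, the median score was 441 for 816 shared peaks and 253 for 20136 unshared ones. In odd replicate 2, it was 481 for 801 shared and 209 for 27975 unshared peaks. Both differences had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give (2e-05 after adjustment over the 4 libraries). The medians differed by 189 in even replicate 2 and 273 in odd replicate 2. For peaks shared with at least 1 other library they differed by 66.9 and 89.5, with the same permutation p. In the replicate 1 lists both medians were 3100 and the test could show no difference. The score is the authors' and was compared only within a list. Resampling took single peaks of a list as independent, so these p-values do not measure repeatability between pulldowns. The comparison was not repeated without the repeated stretches.

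Regions in all 4 libraries lay in or near genes of some classes more often than random placement on the same chromosome gave. A centre in a protein-coding gene was counted only there, and a centre in a lncRNA gene was not counted among other kinds. By this rule, lncRNA genes held 9.49% of the regions against 6.48% ± 0.901 (SD) by chance (adjusted two-sided permutation p = 0.006). Genes of other kinds, such as pseudogenes and small RNA genes, held 3.61% against 1.35% ± 0.425 (adjusted two-sided permutation p = 0.004). A further 14.6% lay outside genes but within 5 kb of one, against 9.71% ± 1.05, and 37.0% lay farther away, against 44.3% ± 1.75 (adjusted permutation p = 0.004 for both). Protein-coding genes held 35.3% against 38.2% ± 1.75, which did not pass (adjusted permutation p = 0.11), and without even replicate 2 their share was above chance, 43.1% against 39.6% (adjusted p = 0.003), while it was below chance without even replicate 1 (34.9%, adjusted p = 0.028) or without odd replicate 1 (36.1%, adjusted p = 0.048). Within 2 kb of an end of a protein-coding gene lay 7.09% against 5.51% ± 0.789 (adjusted permutation p = 0.058), a share that passed when any library was left out (7.55% without even replicate 1, 9.25% without even replicate 2, 9.07% without odd replicate 1 and 8.51% without odd replicate 2) but not within 1 kb (3.48%, adjusted p = 0.37) or without repeated stretches (7.24%, adjusted p = 0.19). Against shifts of 10 to 100 kb none of these classes passed, with adjusted permutation p from 0.06 to 0.66, and the lncRNA share also missed the threshold without odd replicate 2 (8.05%, adjusted p = 0.053). The share within 5 kb of a gene also missed it without repeated stretches (11.8%, adjusted permutation p = 0.20) and when any overlap replaced the region centre (10.7%, adjusted p = 0.22). Among the 7979 regions with at least 1 even and 1 odd library, 8.86% lay within 2 kb of an end of a protein-coding gene, against 5.80% ± 0.259 by random placement and 7.29% ± 0.284 by shifts (adjusted permutation p = 0.002 and 0.004). Their share inside protein-coding genes, 43.4%, exceeded random placement (39.9% ± 0.545, adjusted permutation p = 0.002) but not shifts (42.8% ± 0.389, adjusted p = 0.11).

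Gene lists fixed beforehand were then compared with random lists of the same size and gene length. For regions in all 4 libraries, genes with a region inside or within 5 kb were Lmx1b, a podocyte transcription factor, and Col4a3, a collagen chain of the glomerular basement membrane, of 44 podocyte genes; Dnmt3a, a DNA methyltransferase, and Jarid2, a Polycomb cofactor, of 30 chromatin regulators; the proximal tubule regulator Hnf4a of 25 tubule genes; the VEGF receptor gene Flt1 of 22 mesangial and endothelial genes; and Olfr646 of 1465 olfactory and vomeronasal receptor genes. The region in Jarid2 was at chromosome 13, 44869443 to 44870135, and that in Dnmt3a at chromosome 12, 3846847 to 3847693. In even replicate 2 the median peak score was 265. Regions in Jarid2, Dnmt3a, Lmx1b, Col4a3 and Olfr646 scored below it there, at 110, 234, 192, 246 and 157. Those in Hnf4a and Flt1 scored 324 and 528. In odd replicate 2, with a median of 221, the region in Jarid2 scored 175 and the others lay above the median. No gene of the lists for PGC-1 and its partners (30 genes), oxidative phosphorylation (71), mitochondrial dynamics and mitophagy (25), Hox (39), the p53 pathway (25) or matrix and fibrosis (30) had one, where random lists gave means of 0.605, 0.727, 0.436, 0.388, 0.323 and 0.408 genes, too few for a shortfall to be seen. None of the 11 lists differed from random lists (adjusted two-sided permutation p = 1 for each), and random lists gave means of 1.40 podocyte genes, 0.438 chromatin regulators, 0.415 tubule genes, 0.375 mesangial and endothelial genes and 3.76 receptor genes.

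With regions in at least 1 even and 1 odd library, 9 PGC-1 list genes had a region against 6.60 ± 2.02 (SD) expected, namely Ppargc1a, Ppargc1b, Esrrb, Esrrg, Ppara, Ppard, Pparg, Crtc2 and Mef2c (adjusted permutation p = 0.95). Podocyte genes numbered 14 against 12.8 ± 2.60, among them Wt1, Synpo, Magi2 and Tjp1 (adjusted permutation p = 0.98). Chromatin regulators numbered 9 against 5.37 ± 2.05, including Ezh1, Aebp2, Cbx7 and Hdac1 (adjusted permutation p = 0.78). Oxidative phosphorylation genes numbered 7 against 6.81 ± 2.48, including Ndufs3, Ndufs8 and Atp5pb (adjusted permutation p = 1). Mitochondrial dynamics genes numbered 5 against 5.35, tubule genes 3 against 4.35, mesangial and endothelial genes 2 against 4.36, Hox genes 4 against 3.2, p53 pathway genes 4 against 3.17 and matrix genes 4 against 5.52, with adjusted p from 0.95 to 1. Receptor genes of smell were the exception, with 36 against 62.6 ± 7.63, a ratio of 0.575 (adjusted permutation p = 0.0044). Random members were drawn singly by gene length, without regard to position. Grouping of receptor genes along chromosomes was therefore not allowed for, and this p may be too small. The other 10 lists passed in none of the 9 alternative settings.

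**Figure D3:**
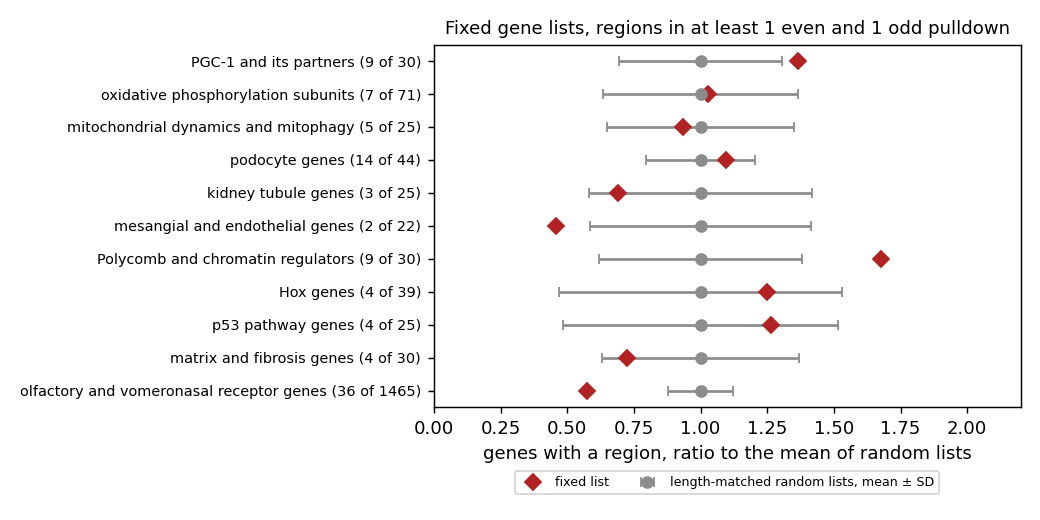
Number of genes of each fixed list with a region of at least 1 even and 1 odd library, as a ratio to the mean of 10000 random lists matched on gene length (red diamonds, counts in the labels). Grey points and bars are the mean ± SD of the random lists, and olfactory and vomeronasal receptor genes, at 0.575, are the only list past the threshold.

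Ppargc1a, which codes for the transcriptional coactivator PGC-1alpha, a regulator of mitochondrial biogenesis, was examined because work on Tug1 in podocytes has followed it up. The gene (gene ID 19017) spans 661605 bp of chromosome 5, from 51454249 to 52115853. No region in the gene or 500 kb to either side was found in all 4 libraries, as was the case in 63.1% of equal windows around other protein-coding genes. The region found in most libraries, at 51959169 to 51959969, lay inside the gene, 505 kb from its low-coordinate and 156 kb from its high-coordinate end. It held peaks of even replicate 1 (score 3100), even replicate 2 (score 374) and odd replicate 1 (score 3100), and the nearest peak of odd replicate 2 lay 24457 bp away. The window held 7 regions of 2 libraries and 63 of 1 library. Its 4 regions with at least 1 even and 1 odd library compare with a median of 5 (quartiles 3 and 8) in equal windows around 21886 other protein-coding genes, of which 25.3% held fewer. With 100 kb to either side the number was 2, against a median of 3. The gene annotation used here gives neither strand nor transcription start sites, so upstream and downstream were not separated. Lying inside the gene span therefore does not show how far the region is from a transcription start of Ppargc1a.

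**Figure D4:**
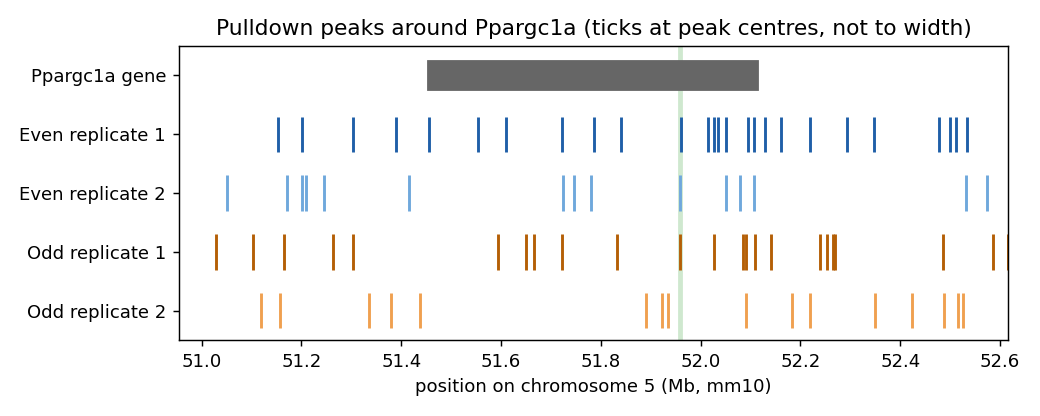
Peak centres of the 4 pulldown libraries (ticks, 1 line per library, not to width) and the Ppargc1a gene (grey bar) on chromosome 5 in Mb of mm10, with 500 kb to either side. The green band marks the region inside the gene with peaks of both even libraries and odd replicate 1, where odd replicate 2 has none.

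Chromosomes 8, 15 and 19 held more peaks per Mb than the other autosomes in all 4 libraries. Relative to the median autosome, density was 1.76 ± 0.232 (SD, n = 4) on chromosome 8, 1.56 ± 0.122 on chromosome 15 and 1.65 ± 0.123 on chromosome 19. The highest value of any other autosome in any library was 1.18. Chromosome X stood at 0.769 and 0.791 in even and odd replicate 1 and at 1.31 and 1.17 in even and odd replicate 2. These ratios describe the peak lists, and the chromosomes were singled out after their values were seen.

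**Figure D5:**
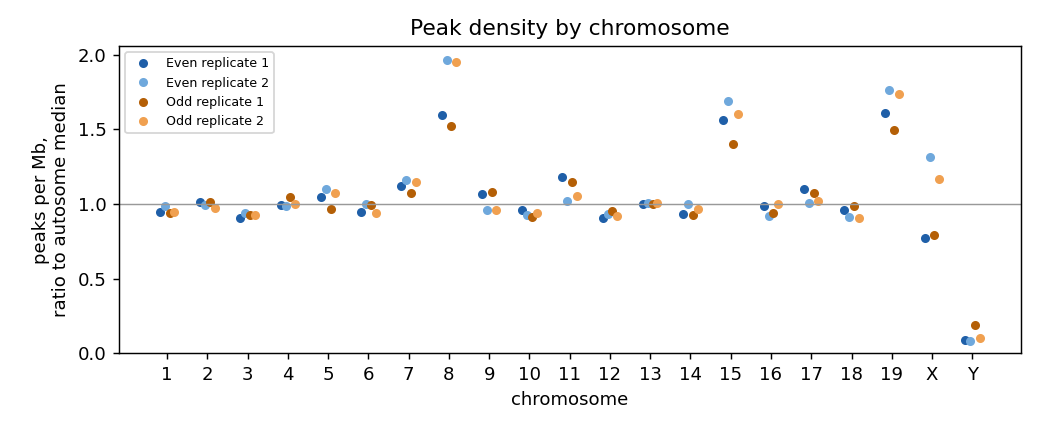
Peaks per Mb on each chromosome divided by the median of the autosomes of the same library (1 point per library, the line marks 1). Chromosomes 8, 15 and 19 lie between 1.40 and 1.97 in all 4 libraries, and chromosome X separates replicates 1 from replicates 2.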

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

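Across 199 recalculated values, 175 were unaltered by a fixed rule, 10 passed the threshold newly, 9 lost it, 4 moved and 1 turned direction. Gene lists gave 99 of these values and 96 of the unaltered ones, and 10 of the 11 lists passed in no setting. For tested values the rule asks for the same side of the threshold and, where called, the same direction, whatever their size; a count moved if it differed by more than 1.5 times. Exclusion of chromosomes 8, 15 and 19 and of listed repeated stretches was chosen after seeing the data. Overlap stayed above chance in every setting run, 10.1-fold to 34.5-fold within probe sets and 7.02-fold to 22.4-fold between them. The 5000 highest-scoring peaks per list could not be taken because more peaks than that score 3100 or above in the replicate 1 lists; for the same reason the median filter keeps most of these lists. The replicate number ties pulldowns to an input library; as a block, same-number pairs alone gave a 10.1-fold even-odd overlap against 9.43-fold for different numbers; the overlap alone does not show that the number pairs libraries, and the block changed no call.

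Leaving out 1 library gave 887 to 1903 common regions, since fewer lists must share them. It gave 34.9% to 43.1% of regions in protein-coding genes, with 43.1%, without even replicate 2, above chance and so turned in direction, 7.55% to 9.25% near ends of protein-coding genes (9.63% with any overlap in place of the centre), and 8.03% to 9.47% in lncRNA genes. Receptor genes of smell had a ratio of 0.288 to 0.477 with 1 library left out, which passed without even replicate 2 (0.288, adjusted permutation p = 0.013) but not without any other library. It also passed with regions of at least 1 even and 1 odd library (0.575, adjusted permutation p = 0.0044) and of both even or both odd libraries (0.490, adjusted permutation p = 0.0022). With 50 kb around the gene it was 0.698 (adjusted permutation p = 0.69), and with 5 kb around either gene end 0.326 (adjusted p = 1). Against shifts of 10 to 100 kb, the shares in lncRNA genes (9.49%), other genes (3.61%), within 5 kb (14.6%) and farther (37.0%) no longer passed, nor did 43.4% in protein-coding and 7.67% in lncRNA genes among even-odd regions. The share within 5 kb also missed the threshold with any overlap (10.7%) and without repeated stretches (11.8%). With 100 kb around Ppargc1a, 2 even-odd regions were found in place of 4. The causes of these changes were not tested, except that shifts keep the regional density of peaks. Read depth is unknown, so its effect could not be examined.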

Other observations

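The tests of small RNA genes, dense clusters, extra copies, shared input and input or batch by number were chosen after the results were seen. Genes of some small structural RNAs recurred among the shared regions. The 5S ribosomal RNA genes on chromosome 8 (48 genes, 123538784 to 123622046) had a peak at 37 and 38 genes in the even and 39 and 44 in the odd libraries. Merged regions of all 4 libraries held 40 of these genes. A gene inside such a region need not itself have a peak of each library. Of 408 tRNA genes, 23 and 16 had a peak in the even and 26 and 21 in the odd libraries, against 2.81, 1.90, 1.51 and 2.58 after random placement (adjusted one-sided permutation p = 0.0015 in each). Regions in all 4 libraries with tRNA genes included n-TLcag9 on chromosome 1 (171101359 to 171102057) and n-TMcat5 on chromosome 13 (23499671 to 23500292). Small nuclear RNA genes with a peak numbered 13 and 7 of 1004 in the even libraries, against 7.9 and 5.32 by chance (adjusted permutation p = 0.063 and 0.29), and 12 and 15 in the odd libraries, against 4.04 and 7.29 (adjusted permutation p = 0.0027 and 0.014). The difference between the probe sets was not tested. Small nuclear RNA genes overlapped 4 regions of all 4 libraries against 0.248 by chance (adjusted permutation p = 0.004). Small nucleolar RNA genes had 0 such regions against 0.3 by chance. Chance for small RNA genes came from random placement, which does not keep the regional density of peaks. No kind of small RNA gene was set alone against shifts, so this limit was not tested for them. The class of other genes, which includes pseudogenes, was. Against shifts of 10 to 100 kb, the class of other genes lost its call in regions of all 4 libraries (3.61%, adjusted permutation p = 0.084). It kept the call among even-odd regions (2.56%, adjusted permutation p = 0.004). The stretch around the small RNA gene Rn4.5s on chromosome 6 held 8 shared regions of 70200 bp in all, the widest being 20740 bp. Repeated genes can collect reads from many copies, and multiply mapping reads were handled in a way not given in the sources used here.

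The 748 regions shared by all 4 lists were weighed against 3 technical sources. Without the 8 listed repeated stretches and chromosomes Y and M, 663 regions were found, 6630-fold over chance; 25 of the shared regions lie at or nearest to Btbd35f or Spin2 genes, multi-copy families on chromosome X, and autosomes without the listed stretches still gave 615 regions. Against shifts that keep the regional density the fold was 65.7, so neither those stretches nor regional density accounts for the sharing as a whole. Even-odd pairs called against different inputs still overlapped 9.43-fold, which argues against errors of 1 shared input as the source of that pairwise overlap. Errors common to both inputs would not show in this comparison and remain open. Other open explanations are repeated sequence elsewhere, chromatin that any biotinylated oligonucleotide or bead may recover, and binding of Tug1 RNA, a hypothesis. No test here separates them without a pulldown of an unrelated RNA.

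The higher peak density on chromosomes 8, 15 and 19 was spread along them: at least 80.0% of 5 Mb bins, in each chromosome and library, lay above the median bin of the other autosomes, which argues against a few dense clusters. After allowing for genes per bin the ratio was still at least 1.41, so gene density does not account for it. A candidate explanation is extra copies of these chromosomes in the immortalised line, with a mean ratio of 1.66; it cannot be told apart from other causes without the input reads, which a caller would normally use to correct for copy number. With these chromosomes omitted, 615 regions were found in all 4 lists and the even-odd overlap was 10.6-fold.

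The replicate 1 lists differed from the replicate 2 lists in both probe sets. The share of peaks with a score of at least 3100 was 80.5% and 99.9% in even and odd replicate 1 and 0.0716% and 0.112% in even and odd replicate 2. The X-to-autosome ratio was at least 0.38 higher in replicates 2, and the input library, batch or depth shared by a number may underlie this but cannot be told apart, since 1 input goes with each number. No biological explanation was tested.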
